A study of Homo sapiens with 9 samples.

How the data were processed

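Bulk RNA sequencing was carried out on 9 libraries of the human glioblastoma line U87, 3 from each of 3 groups of stably expressing cells, per the labels. The cells carried the PCDH vector alone, the R132H mutant of isocitrate dehydrogenase 1 (IDH1mt), or the same mutant with a cysteine replaced by serine (IDH1mt C269S, shortened to C269S). PCDH is the name of the vector in the labels and has nothing to do with the protocadherin genes named among the other observations. Per the labels' protocols, the cells grew in DMEM with fetal bovine serum, total RNA was isolated with an RNeasy Mini kit, and Novogene made and sequenced the libraries. The selection of RNA, the library kit, the read length and the strand setting were not given in the sources used here.

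The deposited count values are whole-number read counts per gene. The submitters' processing notes name HISAT2 version 2.0.5 for alignment, featureCounts version 1.5.0-p3 for counting, and the genome builds GRCh38 and hg38. A separate deposited table holds FPKM values for the same libraries, which the authors scaled by transcript length and library total. Recomputing them showed that each FPKM equals the count divided by length, by library total and by 1 factor per library, between 0.982 and 1.03. These factors ranked the libraries in the same order as the scaling factors of the fit described below. Their origin was not given in the sources used here. The columns named Control, mt and CS were matched to PCDH, IDH1mt and C269S by their names. The 58735 gene identifiers all occur in GENCODE release 29 (Ensembl release 94), and 58724 have the same coordinates there, while 11 differ. Coordinates are those of the deposited count table on GRCh38. Gene counts do not separate reads of overlapping or antisense genes without a stated strand setting, and genes with near-identical copies are uncertain, among them KRT81, SSX1, CD24, HIST1H2BN, the HLA genes, the protocadherin beta genes and the mitochondrial genes with nuclear copies.

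Total counts per library lay between 19108925 and 24803711. Genes were kept by edgeR's filterByExpr on the groups, which left 16874 genes. Libraries were scaled by the trimmed mean of M values (TMM). The 9 libraries entered 1 fit with a mean per group and no covariate, so that all comparisons shared 1 estimate of the spread. Differences were tested with edgeR's quasi-likelihood F test (robust fit) in edgeR version 4.0.16 under R version 4.3.3, and p-values were adjusted by the method of Benjamini and Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. Levels are given as TMM-scaled CPM from edgeR's cpm function, as mean ± SD of 3 libraries. Fold changes are given on the log2 scale with a standard error (SE). This SE was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic.

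A collection of 39 gene lists covered lipid, sugar, amino acid and mitochondrial metabolism, stress and signalling responses, the cell cycle and DNA repair, the extracellular matrix, antigen presentation, and markers of other cell types. Each list was tested against all other genes with camera from limma version 3.58.1, two-sided, with a preset correlation between genes of 0.01 and adjustment over the 39 lists. Camera with an estimated correlation and fry, which asks only whether the members of a list move one way on balance, were run as alternatives. The score of a list in a library is the mean over its genes of log2 CPM (prior count 2) minus the mean of the PCDH libraries. Single values per library were compared with exact two-sided permutation tests.

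The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named for each comparison were IDH1 and, among protein-coding genes with a mean of at least 1 log2 CPM that were called and whose groups did not overlap, up to 10 genes with the largest rise and up to 10 with the largest fall. Named for each list were up to 4 members with the lowest adjusted p, and for genes moved back by C269S the 10 with the lowest larger p in each direction. Members that run against the name of their list, and genes in the other observations, were named after their values were seen. Some members of the lists are not reported here by name.

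The alternatives were DESeq2 size factors in the same fit, library size alone, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the 6 libraries of a comparison alone, the replicate number as a block, each library left out in turn, DESeq2 version 1.42.0, limma-voom, limma on log2 of the deposited FPKM plus 1 or plus 0.1, an adjusted p under 0.01, and edgeR's test against a 1.5-fold change. The mitochondrial genome was left out in a further alternative chosen after the data were seen. For overlaps between comparisons that share libraries, 50 sets of libraries with no effect were simulated. Each gene had its mean CPM over the 9 libraries and its estimated dispersion, the same in all groups, and genes were drawn independently.

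The steps were tested on simulated counts for IDH1mt against PCDH with 16459 genes, of which 200 were changed. EdgeR called 66% of the genes changed 1.5-fold and 82% of those changed 2-fold in the right direction, and called 9 unchanged genes. DESeq2 called 66% and 82% with 13 unchanged genes, and limma-voom 66% and 81% with 11. Camera called the list that had been raised and 1 unchanged list. Of the genes changed 2-fold and returned, 78% were counted as moved back.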

Results

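Transcript levels were measured by RNA sequencing in U87 cells, a human glioblastoma line, that stably carried an empty vector (PCDH), the R132H mutant of IDH1 (IDH1mt), or that mutant with serine in place of a cysteine (C269S). Each group had 3 libraries, with 19108925 to 24803711 counts per library. The series was set up to ask how self-palmitoylation of the mutant enzyme, the attachment of a fatty acid to its own protein, affects gene expression. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. How many selected lines each construct had is not given either. A difference between groups may therefore come from the selected line or its culture as well as from the construct. With 3 libraries against 3, an exact two-sided permutation test cannot go below 0.1. Of 16874 genes tested, 2375 were called between IDH1mt and PCDH, 239 between C269S and PCDH, and 827 between C269S and IDH1mt.

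The IDH1 transcript (ENSG00000138413, chromosome 2, 208236227 to 208266074 on GRCh38), which encodes the cytosolic isocitrate dehydrogenase, was reported first as a check of the labels. It stood at 110 ± 7.96 CPM in PCDH, 676 ± 16.5 CPM in IDH1mt and 738 ± 30.3 CPM in C269S (SD, n = 3 each). It rose 6.12-fold in IDH1mt (log2 fold change 2.61, SE 0.06, adjusted p = 8.4e-25) and 6.68-fold in C269S (log2 fold change 2.74, SE 0.06, adjusted p = 2.4e-25) in edgeR's test. Between the mutants its log2 difference was 0.13 (SE 0.05) and did not pass the test (adjusted p = 0.227). The check therefore sets PCDH apart from the mutants but cannot tell IDH1mt from C269S, whose columns were matched by name alone. The gene count does not separate the introduced transcript from the cell's own.

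**Figure D1:**
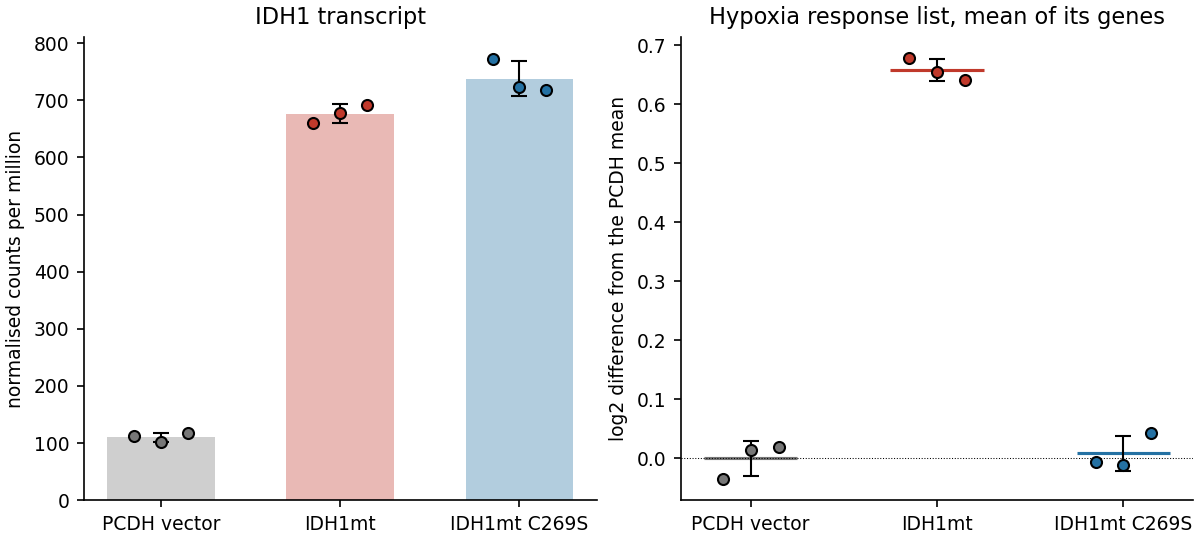
Left, IDH1 level in TMM-scaled CPM, with bars for the group mean, error bars for the SD and a point per library. Right, the mean log2 level of the 31 hypoxia response genes in each library relative to the PCDH mean, with lines for the group mean and error bars for the SD; IDH1 was high in both mutants, whereas the score lay between 0.64 and 0.68 in IDH1mt alone and near 0 in the other groups.

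IDH1mt was compared with PCDH to ask what the R132H mutant changed. No group carried introduced IDH1 without the R132H change. The comparison by itself therefore cannot tell an effect of that change from one of more IDH1. Nor can it tell either from a difference between the selected lines or their cultures. The list of hypoxia response genes rose, as did single genes outside it. SLC2A1, the glucose transporter GLUT1 (ENSG00000117394, chromosome 1, 42925375 to 42959176), rose 3.73-fold from 95.7 ± 4.21 to 357 ± 12.6 CPM (n = 3 each). HILPDA, a lipid droplet protein induced by hypoxia (ENSG00000135245, chromosome 7, 128455849 to 128458418), rose 5.95-fold from 39.4 ± 5.14 to 234 ± 18.6 CPM. ANGPTL4, an inhibitor of lipoprotein lipase, rose from 11.4 ± 1.56 to 70.3 ± 4.27 CPM (log2 fold change 2.63, SE 0.11). DEPP1, a target of FOXO transcription factors (ENSG00000165507, chromosome 10, 44970981 to 44978810), rose 9.07-fold from 22.6 ± 0.880 to 205 ± 7.42 CPM.

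Of the 31 genes of the hypoxia response list, 24 rose, 3 fell and 4 did not pass (28 passed when adjusted over the list alone). NDRG1, a stress-responsive gene, rose 2.40-fold (log2 fold change 1.26, SE 0.06). The members that fell were CA9, a carbonic anhydrase, LOX, a collagen cross-linking enzyme, and NDNF, a secreted neurotrophic factor, with log2 fold changes of -0.22, -0.36 and -0.55, although CA9 and LOX are known targets of hypoxia-inducible factors. The list median was 0.49 and its mean 0.66, and the list rose against all other genes (camera adjusted p = 8.4e-65; adjusted p = 0.00088 with an estimated correlation). Its score per library was 0.66 ± 0.02 above the PCDH mean (exact two-sided permutation p = 0.1, n = 3 each, the smallest possible).

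Of 21 glycolysis genes, 9 rose, 3 fell and 9 did not pass (13 passed when adjusted over the list alone). The rise was led by transporters and hexokinase: besides SLC2A1, HK2, the hexokinase that starts glycolysis, rose 2.56-fold (log2 fold change 1.36, SE 0.05), SLC16A1, a lactate transporter, 1.71-fold, and ALDOA, an aldolase, 1.45-fold. TPI1, LDHB and PFKM, all enzymes of the pathway, fell, with log2 fold changes of -0.22, -0.39 and -0.19. Without PCDH replicate 1 only 1 glycolysis gene passed as lower. The list median of 0.03 lay far below its mean of 0.20 (camera adjusted p = 2.7e-08; adjusted p = 0.153 with an estimated correlation). SLC2A1 is also in the hypoxia list, so the glycolysis and hypoxia lists are not separate. All 15 mitochondrial genome transcripts could be tested, and 12 rose while 3 did not pass (13 adjusted over the list alone). MT-CYB, which encodes cytochrome b, rose 1.48-fold (log2 fold change 0.56, SE 0.06), and MT-ND5, MT-ND6 and MT-ND1, subunits of respiratory complex I, rose 1.32-, 1.34- and 1.33-fold. The median was 0.33 (camera adjusted p = 1.7e-11; adjusted p = 0.153 with an estimated correlation). The share of all counts from the mitochondrial genome was 3.77 ± 0.0437% in IDH1mt and 3.15 ± 0.220% in PCDH (n = 3 each; exact two-sided permutation p = 0.1).

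Several lipid genes rose as well. In the list of fatty acid synthesis, elongation and desaturation, 7 of 28 genes rose and 21 did not pass (11 adjusted over the list alone), among them the desaturases SCD5 (1.28-fold) and FADS3 (1.25-fold) and the acyl-CoA synthetases ACSL3 (1.29-fold) and ACSL1 (1.23-fold). Its median was 0.11 (camera adjusted p = 0.0061; adjusted p = 0.148 with an estimated correlation). In the lipid droplet list, 4 of 21 genes rose and 1 fell (5 adjusted over the list alone): besides HILPDA, LPIN1 (1.39-fold), AGPAT2 and GPAM, enzymes of glycerolipid synthesis, rose, whereas MGLL, a monoglyceride lipase, fell (log2 fold change -0.38). AGPAT2 had a mean of only 1.17 CPM in IDH1mt and was not called by DESeq2, and 2 genes of the list passed as lower without PCDH replicate 3. That list had a median of 0.06 and a mean of 0.30 (camera adjusted p = 0.0013; adjusted p = 0.153 with an estimated correlation). HILPDA, which is also in the hypoxia list, and AGPAT2 lay far above the median, with log2 fold changes of 2.57 and 2.33. Among 38 tested dioxygenases that use 2-oxoglutarate, the substrate from which mutant IDH1 makes 2-hydroxyglutarate, 11 rose and 3 fell (17 adjusted over the list alone). EGLN3 and EGLN1, oxygen-sensing prolyl hydroxylases, rose 3.06-fold and 1.47-fold, KDM3A, a histone demethylase, rose 1.69-fold, and PLOD2, a collagen lysyl hydroxylase, rose 1.26-fold. EGLN3, KDM3A and P4HA1 are also in the hypoxia list. RIOX1, a ribosomal oxygenase, PHF8, a histone demethylase, and PHYH, which oxidises branched fatty acids, fell, and only 1 of the list passed as lower without PCDH replicate 1 or without any 1 IDH1mt library. The median of the dioxygenases was 0.09 (camera adjusted p = 0.0061; adjusted p = 0.153 with an estimated correlation).

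Of 43 DNA replication genes tested, 13 were lower and 30 did not pass (16 adjusted over the list alone), including the helicase subunits MCM5 (log2 fold change -0.41, SE 0.06) and MCM2 (-0.37), the clamp loader RFC4 (-0.43) and the cell-cycle transcription factor E2F1 (-0.34). Its median was -0.17 (camera adjusted p = 7.6e-06; adjusted p = 0.153 with an estimated correlation). Of 47 genes of collagens and the extracellular matrix, 16 fell, 5 rose and 26 did not pass (26 passed when adjusted over the list alone). COL1A2, a chain of type I collagen, fell from 2215 ± 56.4 to 1273 ± 41.4 CPM (log2 fold change -0.80), LOXL1, a cross-linking enzyme, and SPP1, osteopontin, fell by 0.87 and 0.71 on the log2 scale, and LAMB3, a laminin chain, rose 1.73-fold. The median of the list was -0.05 and its mean -0.06 (camera adjusted p = 0.0006; adjusted p = 0.243 with an estimated correlation).

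Signalling genes went both ways. Of 37 NF-kB targets and cytokines, 16 rose, 8 fell and 13 did not pass (24 adjusted over the list alone). The cytokines IL11 (2.06-fold), CCL20 (2.27-fold) and IL6 (1.57-fold) rose, and the chemokine CXCL1 and the adhesion molecule VCAM1 fell, with log2 fold changes of -0.89 and -1.44. Fewer passed as lower without PCDH replicate 1 or IDH1mt replicate 1, 5 in either case. The list median was 0.07 (camera adjusted p = 0.0025; adjusted p = 0.126 with an estimated correlation). Of 32 genes of growth factor feedback and immediate early response, 13 rose and 8 fell (22 adjusted over the list alone). DUSP6, a phosphatase of ERK (1.88-fold), EGR2, a transcription factor (2.25-fold), and EPHA2, a receptor kinase (1.53-fold), rose, and CCND1, cyclin D1, fell (-0.57). The count of lower genes in this list was 5 without PCDH replicate 1 or IDH1mt replicate 1 and 4 without PCDH replicate 2 or IDH1mt replicate 3. Its median was 0.06 (camera adjusted p = 0.0090; adjusted p = 0.181 with an estimated correlation).

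A pair of lists passed only narrowly, each at a camera adjusted p = 0.047. In the TGF-beta and BMP list, 9 of 26 genes rose and 4 fell (16 adjusted over the list alone; median 0.17, mean 0.11; adjusted p = 0.154 with an estimated correlation). The receptor TGFBR1 rose 1.59-fold, whereas ID3 and ID4, inhibitors of DNA binding that BMP signalling induces, fell 2.31-fold and 2.51-fold. This call was lost without PCDH replicate 1 or 2, IDH1mt replicate 3, or C269S replicate 1 or 2 (adjusted p = 0.068, 0.069, 0.065, 0.052 and 0.0504), and with library size alone (adjusted p = 0.084). In the glioma stem cell and neural progenitor list, 7 of 21 genes rose and 1 fell (9 adjusted over the list alone; median 0.04, mean 0.13; adjusted p = 0.153 with an estimated correlation), with CD44, a hyaluronan receptor (1.25-fold), SOX9 (1.49-fold), MSI2 (1.29-fold) and NOTCH2 (1.21-fold) higher, and EZH2, the histone methyltransferase, lower (-0.21), a call kept only without PCDH replicate 3 or C269S replicate 3 when single libraries were left out. This list call was lost without PCDH replicate 1, IDH1mt replicate 2 or C269S replicate 3 (adjusted p = 0.053, 0.063 and 0.058), and without a filter on low counts (adjusted p = 0.077), where the mean of the glioma stem cell and neural progenitor markers list (mean log2 fold change), IDH1mt against PCDH, was -0.35. That mean also took in members with counts too low for the main fit, so it covers a larger set of genes than the 0.13.

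Of the protein-coding genes with a mean of at least 1 log2 CPM and no overlap between the groups, 10 were named for their falls. HGF, the ligand of the MET receptor (ENSG00000019991, chromosome 7, 81699008 to 81770438), fell 4.22-fold from 81.9 ± 7.52 to 19.3 ± 2.24 CPM. FGF7, a fibroblast growth factor, fell 2.48-fold, NR4A2, an orphan nuclear receptor, 2.94-fold, and COL11A1, a fibrillar collagen, 2.59-fold. SSX1, a cancer-testis gene with a mean of 4.16 CPM in PCDH, fell 4.01-fold, and VCAM1, ID3, ID4, HIST1H2BN and ADAMTS2, a procollagen peptidase, were the others. HIST1H2BN lost its call without PCDH replicate 1 or IDH1mt replicate 1 (adjusted p = 0.082 and 0.063). Under the same rule KRT81, a hair keratin, rose from 0.814 ± 0.113 to 12.7 ± 0.203 CPM (15.6-fold), and so did S100A9, a calcium-binding protein (6.73-fold), CD24, a surface glycoprotein (3.76-fold), ACKR3, a chemokine receptor (3.70-fold), and DDIT4L, an inhibitor of mTOR (3.59-fold).

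In edgeR's test 1211 genes were higher and 1164 lower in IDH1mt than in PCDH, with 175 and 92 of them changed over 2-fold and a median change of 1.31-fold among those called. The higher share was 51.0% with TMM scaling and 35.1% with library size alone. The count of genes lower, IDH1mt against PCDH, was 747, 744 and 767 without IDH1mt replicate 1, 2 or 3. Of the 39 lists, 12 were called with the preset correlation and 1, the hypoxia list, with an estimated one. Other splits of these 6 libraries, with 0 genes called, still called up to 6 lists with the preset correlation. A list call that rests on the preset correlation alone is therefore weak.

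**Figure D2:**
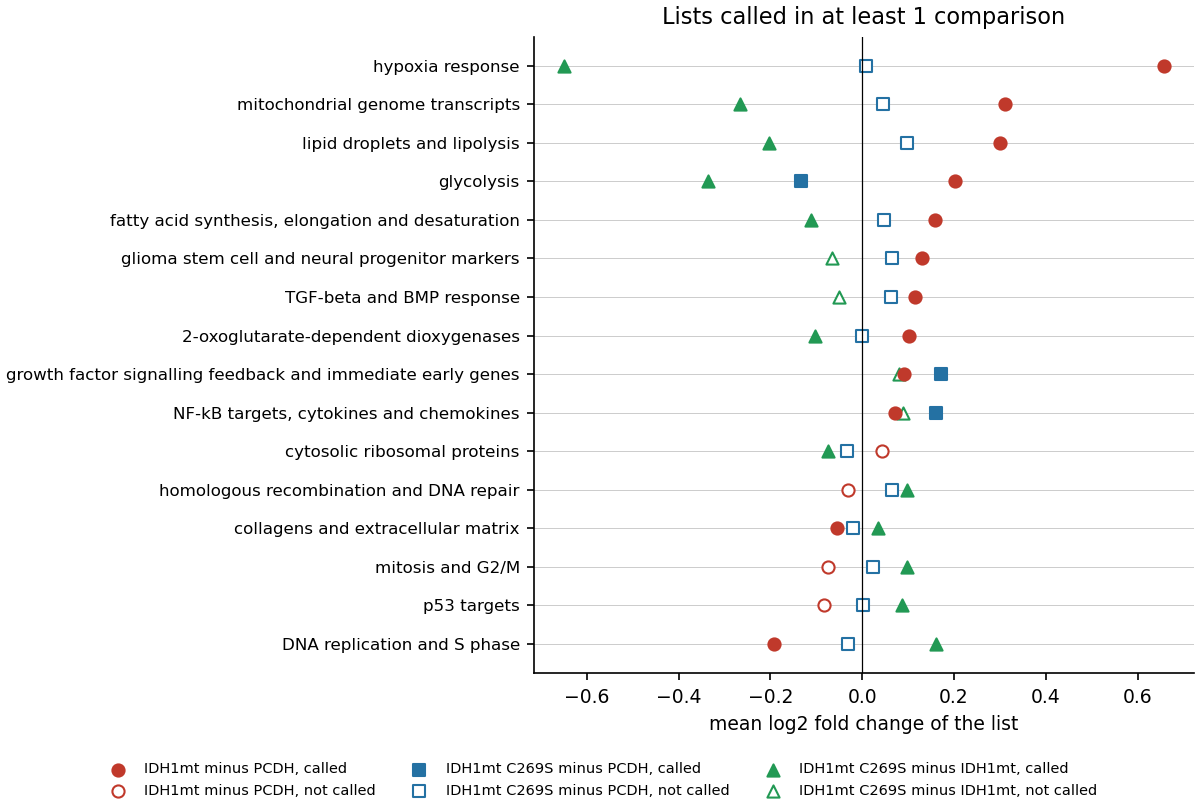
Mean log2 fold change of the 16 lists called in at least 1 comparison, for IDH1mt against PCDH (circles), C269S against PCDH (squares) and C269S against IDH1mt (triangles); filled symbols were called at a camera adjusted p under 0.05 with the preset correlation. The hypoxia list lay at 0.66, 0.01 and -0.65 in these comparisons.

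C269S was compared with PCDH to ask what the mutant changed with the serine in place of the cysteine. Differences between the selected lines or their cultures cannot be told apart from such an effect here. Besides IDH1, genes named by the same rule rose, and those given here were also higher in IDH1mt. PI3, the elastase inhibitor elafin (ENSG00000124102, chromosome 20, 45174876 to 45176544), rose 2.04-fold from 1375 ± 44.6 to 2807 ± 175 CPM (n = 3 each), CD24 rose 2.24-fold, S100A9 2.43-fold and IL11 1.73-fold. SUSD2, a membrane protein, rose 2.27-fold. Among the genes named for their falls, COL11A1 fell 1.95-fold, SLCO2B1, an organic anion transporter, 1.78-fold, KCNE4, a potassium channel subunit, 1.75-fold, ID3 1.53-fold and ADCY8, an adenylyl cyclase, 1.53-fold. SLCO2B1 lost its call without PCDH replicate 1 or C269S replicate 1 or 2 (adjusted p = 0.072, 0.085 and 0.063 in edgeR).

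Of 32 growth factor feedback and immediate early genes, 5 rose in C269S and 27 did not pass (13 adjusted over the list alone): DUSP6 (1.60-fold), DUSP5, another ERK phosphatase (1.36-fold), SPRY4, a feedback inhibitor of receptor kinases (1.29-fold), IER3 (1.18-fold) and the cytokine LIF. The count was 11 without PCDH replicate 3 and 3 without C269S replicate 1 or 3. IER3 lost its call without PCDH replicate 2 or C269S replicate 1 or 3, and SPRY4 without C269S replicate 3 (adjusted p = 0.155, 0.146, 0.077 and 0.069). The median of the list was 0.17 (camera adjusted p = 6.4e-10; adjusted p = 0.054 with an estimated correlation). Of 37 NF-kB targets and cytokines, 10 rose, 1 fell and 26 did not pass (21 adjusted over the list alone), with IL11, CCL20 (1.64-fold), PTGS2, the inducible cyclooxygenase (1.35-fold), and CSF3 (1.19-fold) higher and CXCL1 lower (-0.33). The count of higher genes was 5 without PCDH replicate 2, 4 without C269S replicate 1 and 5 without C269S replicate 2, and the fall of CXCL1 was lost without PCDH replicate 1. The median was 0.22 (camera adjusted p = 4.0e-08; adjusted p = 0.017 with an estimated correlation).

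Of 21 glycolysis genes, 5 were lower in C269S, 2 higher and 14 did not pass (16 adjusted over the list alone). TPI1, triose phosphate isomerase, and the enolases ENO1 and ENO2 had log2 fold changes of -0.29, -0.26 and -0.25, whereas HK2 rose 1.20-fold and SLC2A1 1.21-fold. The count of lower genes was 2 without PCDH replicate 1 or C269S replicate 1 or 2, 3 without PCDH replicate 2 and 9 without PCDH replicate 3. The count of higher genes was 0 without PCDH replicate 1, 3 without PCDH replicate 3 and 1 without C269S replicate 3. Without PCDH replicate 1 HK2 had an adjusted p = 0.054 in edgeR, and ENO2 had adjusted p-values from 0.056 to 0.088 without PCDH replicate 1 or 2 or C269S replicate 1 or 2. The list median was -0.15 (camera adjusted p = 4.5e-05; adjusted p = 0.367 with an estimated correlation). The hypoxia list had a median of -0.02 with 3 genes higher and 2 lower (12 adjusted over the list alone; camera adjusted p = 0.913): ANGPTL4 rose 1.80-fold, SLC2A1 1.21-fold and EPAS1, a hypoxia-inducible factor, by a log2 fold change of 0.22, while CA9 and LOX fell by 0.43 and 0.39 on the log2 scale. Its score was 0.01 ± 0.03 (n = 3; exact two-sided permutation p = 0.8). The mitochondrial share of counts was 3.27 ± 0.0838% (n = 3; exact two-sided permutation p = 0.7 against PCDH).

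In edgeR's test 149 genes were higher and 90 lower in C269S than in PCDH, with 9 and 3 of them changed over 2-fold. The count of genes changed, IDH1mt C269S against PCDH, was 134 without PCDH replicate 1, 134 without replicate 2 and 903 without replicate 3, which lay apart from the other PCDH libraries on the second principal component, and 103 and 125 without C269S replicate 1 or 2. With the libraries of these groups alone it was 145. Of the 39 lists, 3 were called, 7 without PCDH replicate 3 and 5 without C269S replicate 3. When these 6 libraries were split in 10 ways, 7 splits called at least 3 lists and 2 at least 239 genes, the real split among them. Another split called 925 genes, so the gene and list counts for C269S against PCDH are no higher than regrouping gave.

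C269S was compared with IDH1mt to ask what the replaced cysteine changed in the mutant. The comparison by itself cannot tell an effect of that residue from a difference between the selected lines or their cultures. The hypoxia response list, which was higher in IDH1mt than in PCDH, was lower in C269S than in IDH1mt. HILPDA fell 5.63-fold from 234 ± 18.6 to 41.6 ± 3.63 CPM (n = 3 each), DEPP1 7.45-fold from 205 ± 7.42 to 27.5 ± 4.09 CPM, SLC2A1 3.08-fold, ANGPTL4 3.45-fold to 20.3 ± 3.96 CPM, and EGLN3 3.26-fold. KRT81 (10.7-fold), CES1, a carboxylesterase (3.19-fold), and DDIT4L (3.05-fold) fell as well. HGF rose 3.28-fold, FGF7 2.53-fold, NR4A2 by a log2 fold change of 1.32, VCAM1 2.77-fold, and RSPO3, an activator of Wnt signalling, 1.94-fold.

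Of 31 hypoxia response genes, 26 fell and 5 did not pass (28 adjusted over the list alone), with NDRG1 down 2.31-fold and PFKFB3, a regulator of glycolytic flux, down 1.93-fold. Its median was -0.45 (camera adjusted p = 3.7e-113; adjusted p = 0.00014 with an estimated correlation), and the score fell by 0.65 (exact two-sided permutation p = 0.1, n = 3 each). Of 21 glycolysis genes, 11 fell, 1 rose and 9 did not pass (15 adjusted over the list alone). HK2 fell 2.13-fold, SLC16A1 by a log2 fold change of -0.58 and LDHA, lactate dehydrogenase, 1.36-fold, whereas PFKM, a phosphofructokinase, rose by a log2 fold change of 0.23, a call lost without any 1 library of either mutant. The median of the list was -0.30 (camera adjusted p = 5.1e-31; adjusted p = 0.013 with an estimated correlation). Of 15 mitochondrial genome transcripts, 9 fell and 6 did not pass (13 adjusted over the list alone; 5 without IDH1mt replicate 1 or 3), with MT-CYB down 1.36-fold and a median of -0.27 (camera adjusted p = 2.6e-13; adjusted p = 0.135 with an estimated correlation). Of 38 dioxygenases, 9 fell (14 adjusted over the list alone), among them EGLN3, KDM3A (1.45-fold) and PLOD2 (1.33-fold), with a median of -0.06 (camera adjusted p = 0.00023; adjusted p = 0.091 with an estimated correlation).

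Of 43 DNA replication genes, 6 rose (9 adjusted over the list alone), including PCNA, the sliding clamp (1.27-fold), and MCM3 (1.22-fold), with a median of 0.15 (camera adjusted p = 4.9e-07; adjusted p = 0.113 with an estimated correlation). The count was 3 without IDH1mt replicate 1 or 3 and 2 without IDH1mt replicate 2 or C269S replicate 2. Of 39 mitosis genes, CDK1 (1.25-fold), TOP2A (1.19-fold) and AURKB (1.22-fold) rose, 3 in all and 3 adjusted over the list alone; only 1 passed without IDH1mt replicate 1 or C269S replicate 1 and 5 passed without PCDH replicate 3. The median was 0.09 (camera adjusted p = 0.00043; adjusted p = 0.339 with an estimated correlation and 0.067 with fry). Of 27 p53 targets, CDKN1A, the cyclin-dependent kinase inhibitor p21 (1.41-fold), PLK2 (1.31-fold), RRM2B (1.27-fold) and the death receptor FAS (1.32-fold) rose (4 in all, 5 adjusted over the list alone; median 0.06; camera adjusted p = 0.0034; adjusted p = 0.113 with an estimated correlation). The count was 2 without any 1 IDH1mt library or without C269S replicate 1 or 2. Of 31 DNA repair genes, FANCI (1.27-fold) and RAD54L (log2 fold change 0.37) rose, 2 in all and 2 adjusted over the list alone (median 0.08; camera adjusted p = 0.022; adjusted p = 0.248 with an estimated correlation). Only 1 of them passed without IDH1mt replicate 1 or 3 or C269S replicate 1 or 3, and the list call was lost without IDH1mt replicate 1 (adjusted p = 0.077) or C269S replicate 1 (adjusted p = 0.086).

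Of 47 matrix genes, 14 rose and 4 fell between the mutants (24 adjusted over the list alone), with LOXL1 (1.51-fold), TNC, tenascin C (log2 fold change 0.38), and COL1A2 (1.26-fold) higher and LAMB3 lower (-0.40). The list median was 0.02 and its mean 0.03 (camera adjusted p = 0.0022; adjusted p = 0.339 with an estimated correlation), and the call was lost without IDH1mt replicate 1 (adjusted p = 0.069). The lipid droplet list fell, with HILPDA and LPIN1 (1.26-fold) lower and MGLL 1.22-fold higher among 21 genes (4 adjusted over the list alone; median -0.08; camera adjusted p = 0.00051; adjusted p = 0.113 with an estimated correlation). Without a filter on low counts that call was lost (adjusted p = 0.081). In the fatty acid synthesis list, SCD, the stearoyl-CoA desaturase, fell 1.29-fold, and ACSL5 was the other of 2 genes called lower (2 adjusted over the list alone; median -0.06; camera adjusted p = 0.019; adjusted p = 0.113 with an estimated correlation). ACSL5 lost its call without IDH1mt replicate 1 or 3 or any 1 C269S library (adjusted p from 0.081 to 0.395). The list of 75 cytosolic ribosomal proteins was lower on balance with a median of -0.07 (camera adjusted p = 0.00054; adjusted p = 0.541 with an estimated correlation and 0.157 with fry), although RPS21 alone was called (log2 fold change -0.21). The list call was lost without C269S replicate 1 (adjusted p = 0.105). The number of ribosomal genes called was 5 without PCDH replicate 3, 3 without C269S replicate 3 and 2 without C269S replicate 2, and RPS21 itself lost its call without IDH1mt replicate 1 or 3 or C269S replicate 1 or 3 (adjusted p = 0.337, 0.152, 0.252 and 0.106).

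Genes for the enzymes that attach and remove palmitate were examined as a list of 30. In IDH1mt against PCDH, ABHD17C, a depalmitoylase, and ZDHHC9, a palmitoyltransferase, rose and PPT1, a lysosomal thioesterase, fell, with log2 fold changes of 0.42, 0.22 and -0.24, and 27 did not pass (3 adjusted over the list alone). The list medians were -0.03, 0.03 and 0.02 in IDH1mt against PCDH, C269S against PCDH and C269S against IDH1mt (camera adjusted p = 0.981, 0.818 and 0.841).

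In edgeR's test 387 genes were higher and 440 lower in C269S than in IDH1mt, with 22 and 48 of them changed over 2-fold. The higher share was 46.8% with TMM scaling and 60.2% with library size alone. The count of genes changed, IDH1mt C269S against IDH1mt, was 827 and became 450, 514 and 472 without IDH1mt replicate 1, 2 or 3, 465 and 538 without C269S replicate 1 or 2, and 1244 without PCDH replicate 3. Of the 39 lists, 12 were called with the preset correlation, of which the hypoxia and glycolysis lists passed with an estimated one. Other splits of these 6 libraries, with at most 1 gene called, still called up to 7 lists with the preset correlation. A list call that rests on the preset correlation alone is therefore weak.

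The comparisons were then set against each other. Of the genes called in IDH1mt, 691 were called in the opposite direction in C269S against IDH1mt and so moved back, 379 of them higher and 312 lower in IDH1mt. Moved back by C269S names the direction of these calls and not a cause, as construct and selected line were not separated. ERRFI1, a feedback inhibitor of EGFR, was raised 2.62-fold and lowered 2.07-fold, while PPIF, a regulator of the mitochondrial permeability pore, NR1D1, a repressor of the circadian clock, and CDKN1A fell by 0.64, 0.63 and 0.52 on the log2 scale and then rose by 0.59, 0.67 and 0.50. Of the 691, 604 were not called between C269S and PCDH and 86 were still called there in the direction of IDH1mt, such as SLC2A1, HK2 and HGF. PGK1, a glycolytic kinase, was the remaining gene and is described among the results for a closer look. The moved-back genes were 29.1% of the IDH1mt calls and 83.6% of the calls between the mutants, and 1681 IDH1mt calls were not called between the mutants. Independent lists would share 58.3 genes in this way, a value that leaves out the shared IDH1mt libraries. Simulated libraries with no effect gave at most 2, but at most 4 genes were called in them for IDH1mt against PCDH, so neither value is a measure of chance for the 691. The number of genes changed by IDH1mt and moved back by C269S was 395, 432 and 412 without IDH1mt replicate 1, 2 or 3 and 421 without C269S replicate 1.

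In both mutants 217 genes were called in the same direction against PCDH, 137 higher and 80 lower, which was 90.8% of the C269S calls. These calls too do not separate the construct from the selected line or its culture. Examples were IDH1, PI3, IL11, DUSP6, COL1A2 and ADCY8. Independent lists would share 16.9 genes, a value that leaves out the shared PCDH libraries. Simulated libraries with no effect shared at most 1, but so few genes were called in them (at most 4 for IDH1mt against PCDH) that neither value is a measure of chance for the 217. The number of genes changed in both mutants against PCDH in the same direction was 127, 120 and 705 without PCDH replicate 1, 2 or 3, 96 and 114 without C269S replicate 1 or 2, and 129 when each comparison was fitted on its own libraries. Across genes, the log2 fold changes of the mutants against PCDH had a correlation of 0.572, where the shared PCDH libraries alone gave 0.497, and a covariance of 0.0773, where they gave 0.0329. The changes of IDH1mt against PCDH and of C269S against IDH1mt had a correlation of -0.659 (simulated -0.498) and a covariance of -0.0969 (simulated -0.0330). Genes are not independent replicates, and as 3 libraries cannot be split into 2 sets of at least 2, part of either excess may come from the shared libraries. The simulation gave all groups the same dispersion, whereas PCDH replicate 3 lay apart from the other PCDH libraries on the second principal component. Its values for the shared PCDH libraries may therefore be too low.

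**Figure D3:**
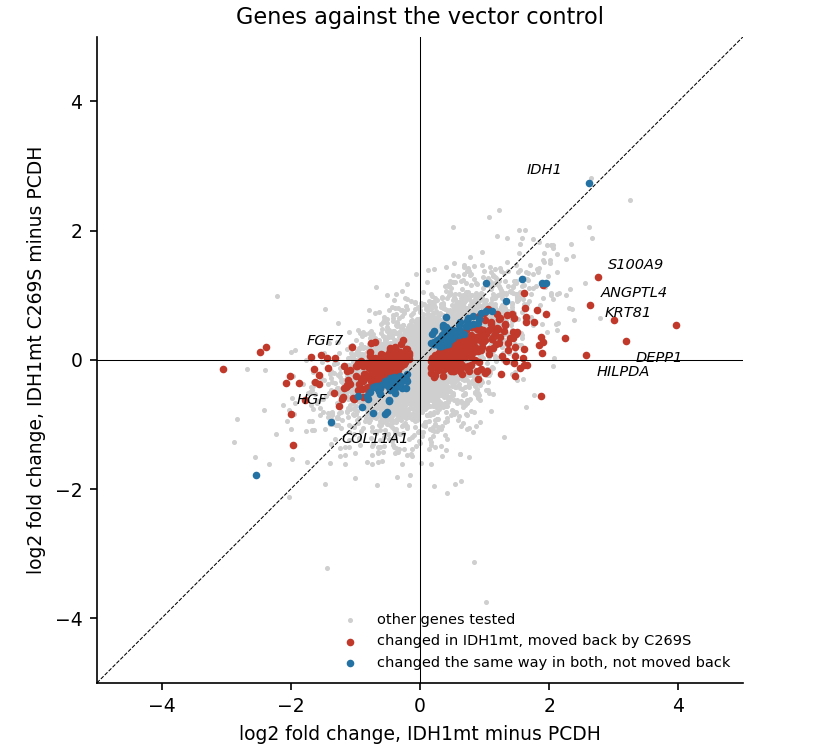
Log2 fold change against PCDH of each tested gene in IDH1mt (horizontal axis) and in C269S (vertical axis), with the line of equal change dashed. Red points are the 691 genes moved back by C269S, and blue points the 131 genes changed in the same direction in both mutants and not moved back.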

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

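The tests in this part were chosen after the results were seen. PGK1, the phosphoglycerate kinase of glycolysis, was picked out because it was called in opposite directions in the mutants against PCDH and also between the mutants. Its log2 fold change was 0.18 in IDH1mt (adjusted p = 0.0122) and -0.21 in C269S (adjusted p = 0.0178), and it was -0.39 in C269S against IDH1mt, in edgeR's test. The glycolysis list was picked out for the same reason, with a median of -0.30 in C269S against IDH1mt. Its calls against PCDH were both lost with an estimated correlation (camera adjusted p = 0.153 in IDH1mt and 0.367 in C269S), and its median in IDH1mt was only 0.03.

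A technical cause could lie in the scaling of the libraries, which would bring the list mean of C269S against PCDH to 0 or above under another scaling. Its highest mean over the 3 scalings was -0.13, but the other scalings moved all genes by only 0.0037 and -0.0189, too little to bring the mean to 0, so this decides nothing and scaling stays open. A single vector library could also shift the list, but the highest mean without 1 PCDH library was -0.11. TPI1 was called lower and HK2 and SLC2A1 were called higher in both mutants against PCDH, so these genes did not differ in direction between the mutants.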

How the results depend on the processing

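Of 166 results for named genes, all kept their direction and 31 lost the call at least once. These were the genes named for the largest changes or as moved back, and the examples of lists called in that comparison. Genes named only for other reasons, such as EZH2, were not followed in this count. Named genes were not followed at an adjusted p under 0.01 or against a 1.5-fold change, so the 31 leave out losses there. The rise of SLC2A1 in C269S against PCDH (adjusted p = 0.018 in edgeR's test), for example, would be lost at 0.01. With library size alone the balance of the calls turned, with the higher share going from 51.0% to 35.1% for IDH1mt against PCDH and from 46.8% to 60.2% for C269S against IDH1mt. The mean of 1 list, glioma stem cell and neural progenitor markers list (mean log2 fold change), IDH1mt against PCDH, went from 0.13 to -0.35 without a filter on low counts, where it was not called. Without that filter more members with low counts entered the mean, so these values cover unlike sets of genes. Counts of calls moved most, and the cause was not tested. The number of genes changed, IDH1mt against PCDH, went from 2375 to 1616 to 3048 with 1 library left out, 1582 with limma on log2 of FPKM plus 0.1, 1310 at an adjusted p under 0.01 and 119 beyond 1.5-fold. For genes changed, IDH1mt C269S against PCDH, 239 became 145 with the compared groups alone, 103 to 903 with 1 library left out (134 without PCDH replicate 1 or 2, 125 without C269S replicate 2), 85 and 87 with FPKM plus 1 and plus 0.1, 100 at 0.01 and 4 beyond 1.5-fold. For genes changed, IDH1mt C269S against IDH1mt, 827 became 450 to 1244 (514, 472, 465 and 538 without IDH1mt replicate 2 or 3 or C269S replicate 1 or 2), 443, 445, 413 and 32. The 217 genes changed in both mutants against PCDH in the same direction became 129 with the compared groups alone, 96 to 705 with 1 library left out (127, 120 and 114 without PCDH replicate 1 or 2 or C269S replicate 2), 77, 78, 87 and 4. The 691 genes changed by IDH1mt and moved back by C269S became 395 to 924 (432, 412 and 421 without IDH1mt replicate 2 or 3 or C269S replicate 1), 387, 390, 358 and 29. Of 12 lists called for IDH1mt against PCDH, 1 was left with an estimated correlation, and fry called 21. Of 3 for C269S against PCDH, 1 was left, fry called 6, library size alone gave 6, no filter 7, and leaving out 1 library 3 to 7 (5 without C269S replicate 3). Of 12 for C269S against IDH1mt, 2 were left and fry called 20, without the mitosis (adjusted p = 0.067) and ribosomal protein (adjusted p = 0.157) lists. With 1 library left out, the IDH1 log2 fold change, IDH1mt against PCDH, was 2.56 to 2.66, and the IDH1 log2 fold change, IDH1mt C269S against PCDH, was 2.69 to 2.79.

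With the replicate number as a block, 1987, 172 and 605 genes were called for the 3 comparisons, of which 1962, 167 and 602 were called without it; the block gave 155 shared and 519 moved-back genes. Libraries with the same number did not pair, with correlations of -0.087 to 0.056 between them and -0.037 to 0.072 between other numbers. Leaving out the mitochondrial genome, chosen after the data were seen, gave 2356 genes changed, IDH1mt against PCDH, 240 genes changed, IDH1mt C269S against PCDH, and 814 genes changed, IDH1mt C269S against IDH1mt.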

Other observations

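Genes of antigen presentation went apart by class in IDH1mt, and were named after their values were seen. Of 10 class II members, 8 rose in edgeR's test, with a median log2 fold change of 0.51, among them HLA-DRA, which presents peptides to helper T cells (0.76), CD74, the invariant chain (0.62), and CIITA, the class II transactivator (0.60). Of 15 class I members, 8 fell and 1 rose, with a median of -0.27, among them HLA-B (-0.50), B2M, the light chain of class I (-0.28), and TAP1, a peptide transporter (-0.40), while ERAP1, a peptide-trimming enzyme, rose (0.27). In C269S the medians were 0.12 and -0.04 against PCDH. The HLA genes share reads with near-identical copies and are uncertain.

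The antigen presentation list as a whole did not pass (camera adjusted p = 0.0686). The split by class was made after the classes were seen to differ, so its test restates what prompted it and decides nothing: the medians differed by 0.77 (two-sided permutation p = 0.00011 over 100000 relabellings of members, with genes and not libraries as units).

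Protocadherin beta genes on chromosome 5, which are unrelated to the vector called PCDH, were looked at after their values were seen and were no fixed list. Of 15 tested, 8 were called lower in IDH1mt and 7 were not called, with a median of -0.69, and PCDHB5 fell by 1.56 on the log2 scale. Of 16489 other runs of 15 neighbouring genes, 0 held as many (0%), and the most in another run was 6, but the cluster was picked for its lower genes, so this scan decides nothing. The members are near-identical copies that can share reads, and so are not separate units. In C269S the median was -0.09 against PCDH, and 3 rose against IDH1mt.

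Markers of other cell types were examined for mixed samples. For IDH1mt against PCDH none of these lists passed with camera, whose adjusted p was 0.461 for astrocytes, 0.865 for neurons, 0.153 for oligodendrocytes, 0.187 for epithelial cells, 0.334 for blood cells, 0.442 for endothelial cells and 0.967 for melanocytes. Fry called the oligodendrocyte (adjusted p = 0.0192) and epithelial (adjusted p = 0.0232) lists higher. The members called higher in edgeR's test were CD44 and GJA1 (astrocytes), SNAP25 (neurons), PDGFRA and MYRF (oligodendrocytes; 1.22 and 0.71), KRT7 and ELF3 (epithelial cells; 2.02 and 0.79) and CSF1R (blood cells; 0.88). Those called lower were APOE (astrocytes; -0.81), NCAM1 and MAP2 (neurons; -0.38 and -0.55) and KDR and TIE1 (endothelial cells; -0.79 and -0.70).

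The hypoxia list was weighed against technical causes, of which the correction for base content was fixed before the data were seen and the others were chosen after. After correction for GC content and transcript length its median in IDH1mt was 0.490. The fitted trend was small over all genes (SD 0.032), so a trend of this kind shared by all genes was not the cause. The median in C269S was -0.018 at a similar IDH1 level, which argues against the amount of IDH1 transcript alone. That value was known when the comparison was chosen. The count does not separate the introduced transcript from the cell's own, and protein was not measured here. Culture density, oxygen in the dishes or a single selected line per construct could give the same pattern: the lowest IDH1mt library scored 0.641 and the highest PCDH library 0.0202, which cannot tell these apart. The 24 raised genes kept a median of 6.58% of their change in C269S, against 46.8% (32.7% to 58.3%) in matched sets of other raised genes (permutation p = 0.0001, the smallest that 10000 sets can give). That comparison was made after the list was seen to lie near 0 in C269S and treats genes regulated together as separate units, so it decides nothing.

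The mitochondrial transcripts were weighed in the same way, with the nuclear comparison chosen after the result was seen and the others before. Correction for GC content and length left a median of 0.336. More mitochondria overall might raise nuclear respiratory genes alike, but their upper quartile was 0.0966, below the lower quartile of 0.232 of the mitochondrial transcripts. A uniform carry-over of mitochondrial RNA would change all transcripts alike, but their changes differed (heterogeneity chi-square 41.9, df 14, p = 0.00013 from the SEs of edgeR's test). This argues against a uniform carry-over as the whole cause. The chi-square treats transcripts of the same libraries as separate units, and a carry-over that differs between transcripts was not tested.

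Regrouping the libraries was fixed before the data were seen. For IDH1mt against PCDH, 1 of 10 splits, the real one, gave 2375 genes and the highest other 0; for C269S against IDH1mt 1 of 10 gave 827 and the highest other 1. For C269S against PCDH 2 of 10 gave at least 239, and the other gave 925 by setting PCDH replicate 3 with C269S replicates 1 and 2. For lists, 1 of 10 splits reached 12 for IDH1mt against PCDH (highest other 6), 7 of 10 reached 3 for C269S against PCDH (highest other 5), and 1 of 10 reached 12 between the mutants (highest other 7). These splits are too few for a share under 0.05. Of 100 splits of the 9 libraries, the real one and 99 drawn, 3 gave at least 217 shared genes and 1, the real one, gave at least 691 moved-back genes, with 560 as the highest other count for each. The drawn splits that reached 217, with 560 and 460 genes, both kept the 3 IDH1mt libraries together, and the other draws gave at most 1. The split with 560 set the IDH1mt libraries against all others and so carried the real IDH1mt difference. Keeping them together was not enough, as other draws that did so gave 0 or 1. The split with 460 also set PCDH replicates 1 and 2 with C269S replicate 3 against PCDH replicate 3 with C269S replicates 1 and 2. That is the grouping that gave 925 genes.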
